A study of Mus musculus with 3 samples.

How the data were processed

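Mouse embryonic stem cells of 3 genotypes were grown into embryoid bodies, the floating cell aggregates in which stem cells differentiate, and endothelial cells were collected at day 4.75. Per the labels, the groups were wild type (WT), a knockout of Scl (the gene whose current symbol is Tal1; SclKO) and a knockout of Gata1 and Gata2 (labelled Gata12KO), with 1 library per group and 3 libraries in all. Cells were sorted as Tie2 positive, CD31 positive and CD41 negative, per the labels' protocols. Total RNA was made into libraries with a Nugen Encore Complete kit and sequenced as 50 nt reads on an Illumina HiSeq, per the labels' protocols. Whether strand was used in quantification is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart.

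The deposited values are FPKM, fragments per kilobase of transcript and per 1M (mega) mapped fragments, written by Cufflinks per the files' source column. TopHat2 2.0.4, Cufflinks 2.0.1 and Cuffdiff, and the builds mm9 and hg19, are named in the submitters' processing notes with no role given for each. Chromosome names in the files fit mm9, so coordinates are printed as the files give them, on mm9. Each file lists 30123 RefSeq entries with the FPKM, its lower and upper confidence bound and its coverage, as deposited by the authors. No scaling between libraries beyond FPKM is stated. Entries carry RefSeq accessions and no symbols. Symbols were taken from the RefSeq gene table of the reference given with the data, and from the GENCODE accession table where that one had none. Of 29646 accessions, 29063 were named by the first table, 173 by the second and 410 by neither. The reference is of another build and was used for symbols and for the GC content of transcripts only. Of the entries, 136 carried another accession in the Gata12KO file and were joined by position and exon structure. A set of 134 entries whose symbols then differed was left out. A gene's FPKM and bounds are the sums over its entries, which gave 23397 genes, of which 403 have only an accession.

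Depth was read from the values. The deposited bounds lie 2 Poisson standard deviations from each FPKM, which gives the reads behind each entry. For entries of at least 100 reads these fitted a single total and a single fragment-length term per library, with 94.5%, 94.5% and 94.4% of entries within 1% of the fit in WT, SclKO and Gata12KO. The implied totals were 31.6, 28.3 and 50.3M fragments, with length terms of 187, 199 and 168 nt. Reads on named entries came to 16.5, 14.6 and 25.0M. The bounds cover counting error alone. They leave out differences between cultures and between library preparations, and with 1 library per group no replicate check of any difference was possible, no p-value is given and no paired analysis applies.

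Ratios are log2((FPKM + 1)/(FPKM + 1)), a scale that understates the ratio of genes with low values. A gene was called higher or lower when its FPKM was at least 1 in any library, its ratio was at least 2-fold, and the deposited bounds of both libraries did not overlap. Both words describe these libraries only. By that minimum 11080 genes were expressed, 10992 of them with a transcript of 300 nt or longer. The rule was tested on libraries of 23397 genes, simulated with Poisson noise at the implied depths from the values of each comparison's reference library. It called 100% of genes simulated at 2.5-fold and 4-fold from a level of at least 10 FPKM in each comparison, which says nothing of genes at lower levels. It called 1 unchanged gene in SclKO against WT and 0 in the others. The bounds assume the same Poisson noise, so few such calls follow by construction. With the log-normal noise described below added, libraries equal to WT had on average 10.5 higher and 11.5 lower calls as SclKO, and 9.96 and 9.62 as Gata12KO.

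Named genes were fixed before the data were examined, as were 19 gene lists, the size rule and most of the alternatives. The rule took the targeted genes in every library, Gata3 to Gata6, the 10 highest and 10 lowest genes of each comparison (FPKM of at least 5 in the higher library, separate bounds, a transcript of 300 nt or longer, no unnamed gene models or small RNA genes), and up to 4 members of each list with the largest ratios. A few more list members were chosen after their values were seen. In SclKO against WT they are Cdh5, Pecam1, Eng, Etv2, Erg, Nfatc1, Has2, Tbx20, Nkx2-5, Snai2, Sox17 and Dll4. In Gata12KO against WT they are Alas2, Myct1, Lyl1, Hhex, Itga2b, Lcp1, Cdh5, Tek and Nos3. In Gata12KO against SclKO they are Mef2c, Nfe2, Spi1, Myb and Runx1. The targeted genes were kept out of every list. For each list the median ratio of members with FPKM of at least 1 in any library was set among medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile under 2.5 or over 97.5 is described as outside the middle of the random lists. It describes these libraries and is no test across samples. Hbb-b1, Ahsp, Cd68 and Polr2a, members of 3 lists, found no matching symbol and were not used here.

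SclKO and the library labelled Gata12KO share the WT library. For their overlap of calls and the correlation and covariance of their ratios, 100 draws were simulated in which both equal WT. Each draw held Poisson noise and a log-normal part. The standard deviation of that part, 0.25 (log2), came from the spread of ratios between these libraries over genes with FPKM of at least 5 in every library. Alternatives tried were other pseudocounts and expression minimums, rescaling by median ratios or to the library sum (TPM), the most abundant transcript per gene, no condition on bounds, a 4-fold rule, leaving out transcripts under 300 nt, all measured list members and unmatched random lists. After seeing the data, removal of the trend of ratios with transcript length (running medians over 40 bins), removal of length and GC trends together (96.8% of expressed genes had a GC value), rescaling over transcripts of 300 nt or longer, and a minimum taken without the library labelled Gata12KO were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.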

Results

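RNA of sorted endothelial cells from day 4.75 embryoid bodies was compared between WT, SclKO and Gata12KO libraries, 1 of each, to find genes that depend on Scl or on Gata1 and Gata2. Scl (Tal1) is a transcription factor required for all blood formation, and Gata1 and Gata2 are zinc-finger factors that act with it in blood cells. Depth in WT, SclKO and Gata12KO was 31.6M, 28.3M and 50.3M fragments, as implied by the deposited bounds. There were no replicates, so every difference below describes these 3 libraries, and the bounds given cover counting error alone.

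The targeted genes were looked at first. Tal1, at chromosome 4, 114732132 to 114744360 on the forward strand of mm9, is given as 1 transcript of 4 exons. It had 51.0 FPKM in WT (bounds 49.7 to 52.3), 1.59 in SclKO (1.35 to 1.83) and 38.7 in Gata12KO (37.8 to 39.6), so that SclKO held 32.1-fold less than WT. Gata1, at chromosome X, 7536386 to 7544941 on the reverse strand with 6 exons, had 4.64 FPKM in WT (4.04 to 5.25), was listed at 0 in SclKO and had 5.66 in Gata12KO (5.13 to 6.18). Gata2, at chromosome 6, 88148658 to 88157026 on the forward strand with 6 exons, had 12.05 FPKM in WT (11.3 to 12.8), 5.81 in SclKO (5.29 to 6.33) and 44.9 in Gata12KO (43.9 to 46.0). Neither Gata1 nor Gata2 was lower than WT in the library labelled Gata12KO, so these levels do not show the knockout that its label names. Each value covers the whole transcript, so a deleted exon would not show in it, and that library is called "the library labelled Gata12KO" from here on. Of the other GATA factors, in WT, SclKO and that library in turn, Gata3 had 6.09, 16.3 and 4.37 FPKM, Gata4 5.57, 9.94 and 8.60, Gata5 0.772, 1.72 and 1.13, and Gata6 17.0, 34.0 and 18.2.

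**Figure D1:**
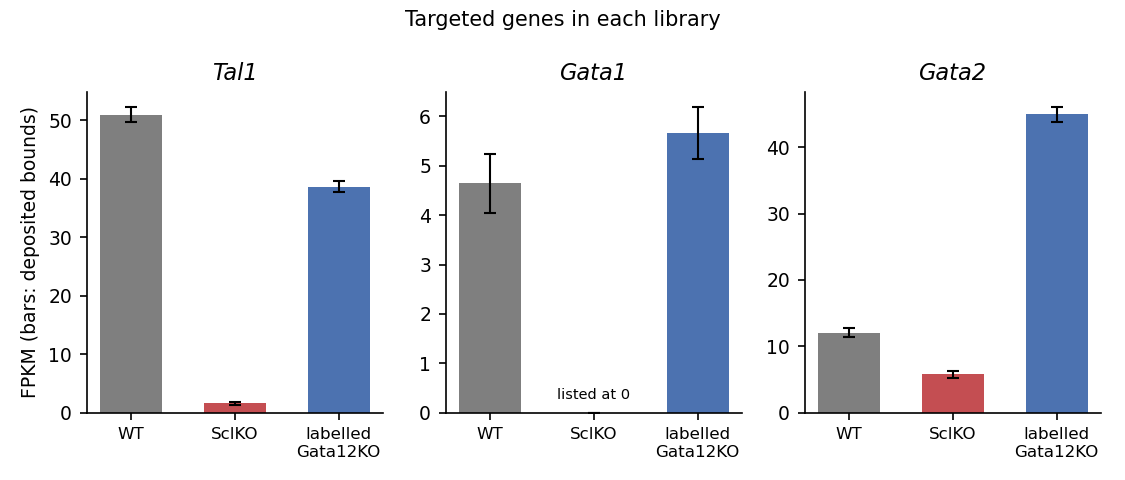
FPKM of the targeted genes Tal1, Gata1 and Gata2 in the WT, SclKO and Gata12KO libraries (1 library each), with a separate linear axis per gene and error bars for the deposited confidence bounds. Tal1 stood at 1.59 in SclKO against 51.0 in WT, whereas Gata1 and Gata2 stood at 5.66 and 44.9 in the library labelled Gata12KO, against 4.64 and 12.05 in WT.

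In SclKO against WT, which asks for genes that depend on Scl, many blood and endothelial transcripts were lower. Of mesenchymal transcripts 5 of 18 were higher and 0 lower, and cardiac lists held calls in both directions. Of 11080 expressed genes, 235 were higher and 470 lower in SclKO. The embryonic globins Hba-x (71.3 FPKM in WT and 0.0881 in SclKO) and Hbb-bh1 (76.8 and 0.258) had the lowest ratios. They were followed by Grb10, an imprinted adaptor of growth factor receptors (46.1 and 0.279), Tal1 itself and Gap43 (81.8 and 3.24). At the other end stood Hsd11b2, which inactivates glucocorticoids (10.4 FPKM in WT and 75.9 in SclKO), and Cdx2, a caudal homeobox factor (1.68 and 16.7).

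Among hematopoietic transcription factors, 10 of 17 expressed members were lower in SclKO, 1 was higher and 6 lay between. Lower members included Runx1, a factor needed for blood cells to leave endothelium (4.56 FPKM in WT and 0.452 in SclKO), Lyl1, a close relative of Scl (21.3 and 1.35), Myct1 (23.6 and 0.891) and Nfe2 (8.60 and 0.217). Myct1 was part of the planned list but is not an established transcription factor. Gata3 was the higher member (6.09 and 16.3). The list's median log2 ratio was -1.94, below all of the random lists. Erythroid genes were lower in 10 of 11 members, with a median of -1.80. Hba-a2 had 15.4 FPKM in WT and Hbb-y 7.89, and both were listed at 0 in SclKO. Globin genes have near-identical copies, so the split of reads between them is uncertain. Megakaryocyte and platelet genes were lower in 8 of 11 members, with a median of -1.50. Among them, Itga2b, which encodes the CD41 used to exclude cells in the sort, had 22.8 FPKM in WT and 0.333 in SclKO. Pan-leukocyte and myeloid genes were lower in 7 of 11 members, with a median of -1.31, including the granule enzyme Mpo (10.2 and 0.286) and the stem cell antigen Cd34 (18.9 and 5.61). All 3 of these medians lay below all of the random lists. Values of a sorted pool do not tell whether each cell held less of these blood transcripts or fewer cells held them. This was not tested. Over all measured members, among them genes near 0 in each library, the medians of the 4 blood lists in this order were -0.64, -0.29, -0.41 and -0.26.

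Pan-endothelial genes were lower in SclKO for 17 of 27 members, with 10 between and none higher. The list's median was -1.14, below all of the random lists. Endothelial nitric oxide synthase Nos3 had 17.7 FPKM in WT and 2.31 in SclKO, the junction protein Esam 88.0 and 14.9, VE-cadherin (Cdh5) 116 and 42.9, and the ETS factor Fli1 39.5 and 12.2. Not all members went that way. The sorting antigen Pecam1 (CD31) had 48.3 FPKM in WT and 50.4 in SclKO, Eng 28.2 and 46.0, and Etv2, an early regulator of blood and endothelial fate, 49.0 and 70.4. Of Scl complex partners, 5 of 16 were lower with a median of -0.41 (percentile 0.15), namely Lyl1, Cbfa2t3 (7.64 and 0.664), Runx1, Fli1 and Erg, all of which are also in the hematopoietic or pan-endothelial list. Endocardial genes split, with 5 of 11 lower, 3 higher and a median of -0.95, below all of the random lists. Removing the length trend took Tgfb2 (1.01 became 0.95) and, among the 17 lower pan-endothelial genes, Ramp2 (-1.14 became -0.82) below the 2-fold limit, as it did Hbb-b2 (-1.18 became -0.90) and Spink1 (-1.04 became -0.92) of the erythroid and endoderm lists. Nfatc1, a factor of endocardium and valves (13.7 and 4.01), and Hapln1 (64.0 and 21.0) were lower, and Cdh11 (4.46 and 25.9) and Has2 (12.7 and 31.2) were higher. Some lists share members, as Cdh11 is also in the mesenchyme list and Tie1 in the pan-endothelial list. Arterial and Notch genes had 2 of 17 higher, Unc5b (6.33 and 21.8) and Foxc1 (1.65 and 5.07), with a median of 0.41 (percentile 99.97). None was lower by the size rule, and the 15 between went in both directions. Among these, Nrp1 (0.99) and Hes1 (0.94) had positive log2 ratios, while Sox17 (-0.79) and Dll4 (-0.72) had negative ones. Venous and lymphatic genes had 1 of 10 higher, Ackr3 (5.26 and 15.9), and 1 lower, Stab1 (3.14 and 0.188), with a median of -0.32 (percentile 2.16, or 3.78 among unmatched lists).

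Cardiac transcription factors and progenitor genes had a median of 0.62 in SclKO against WT, above all of the random lists, although by the size rule 2 of 18 members were higher, 2 lower and 14 between. Hand1, a factor of heart and extraembryonic mesoderm, had 72.2 FPKM in WT and 209 in SclKO, and Irx3 had 2.71 and 16.9. Gata6 had 17.0 and 34.0, Tbx20 14.5 and 24.8, and Gata4 5.57 and 9.94. The lower members were Fgf10 (8.49 and 0.913) and Mef2c (5.09 and 1.77). Nkx2-5 had 3.29 and 4.03. Of the cardiac contractile and cardiomyocyte genes, 12 of 37 were expressed, with 2 higher, 1 lower and a median of 0.19 (percentile 93.5, and 98.8 after the length trend was removed). Higher members were Tpm1 (123 and 261) and Tnni1 (10.2 and 26.3), and Cox7a1 was lower (27.1 and 6.07). Smooth muscle and mesenchyme genes were higher in 5 of 18 members, with none lower and a median of 0.67, above all of the random lists. They were Foxf1 (0.722 and 9.46), Cdh11, Col3a1 (1.39 and 8.06), Pdgfrb (2.39 and 9.16) and Snai2 (11.3 and 31.8). Primitive streak and early mesoderm genes had a median of 0.49 (percentile 99.7), which turned to -0.0051 over all measured members, with Cdx2 and Bmp4 (9.44 and 22.7) higher among 9 members.

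Of the lists for other cells and states in SclKO against WT, endoderm and epithelial genes had a median of 0.26 (percentile 96.3, and 99.2 after the length trend was removed), pluripotency genes -0.12 (32.5, with 0.14 after the length trend was removed) and neuroectoderm genes -0.19 (26.8, over 3 members). Dppa4, expressed in stem cells, stood out with 25.2 FPKM in WT and 2.28 in SclKO. Proliferation genes had 0 of 21 members higher or lower and a median of 0.14 (percentile 99.1, or 94.7 among unmatched lists). Immediate early and stress genes had a median of -0.23 (percentile 6.92) and 0 of 18 members past the rule. Housekeeping genes had a median of -0.19 (percentile 35.3), with Pgk1 (906 and 405) and B2m (119 and 48.0) lower, the call of B2m ending after the length trend was removed (-1.29 became -0.96). Of the higher and lower genes together 66.7% were lower, a share that became 51.7% when libraries were rescaled to their summed FPKM over transcripts of 300 nt or longer, with 640 higher and 686 lower. Setting that sum to 1M raised every value while the pseudocount stayed at 1, and both counts rose. The scaling between libraries was not separated from the smaller weight of the pseudocount. Rescaling to the library sum (TPM) moved it the other way, to 75.9%, with 192 higher and 605 lower.

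**Figure D2:**
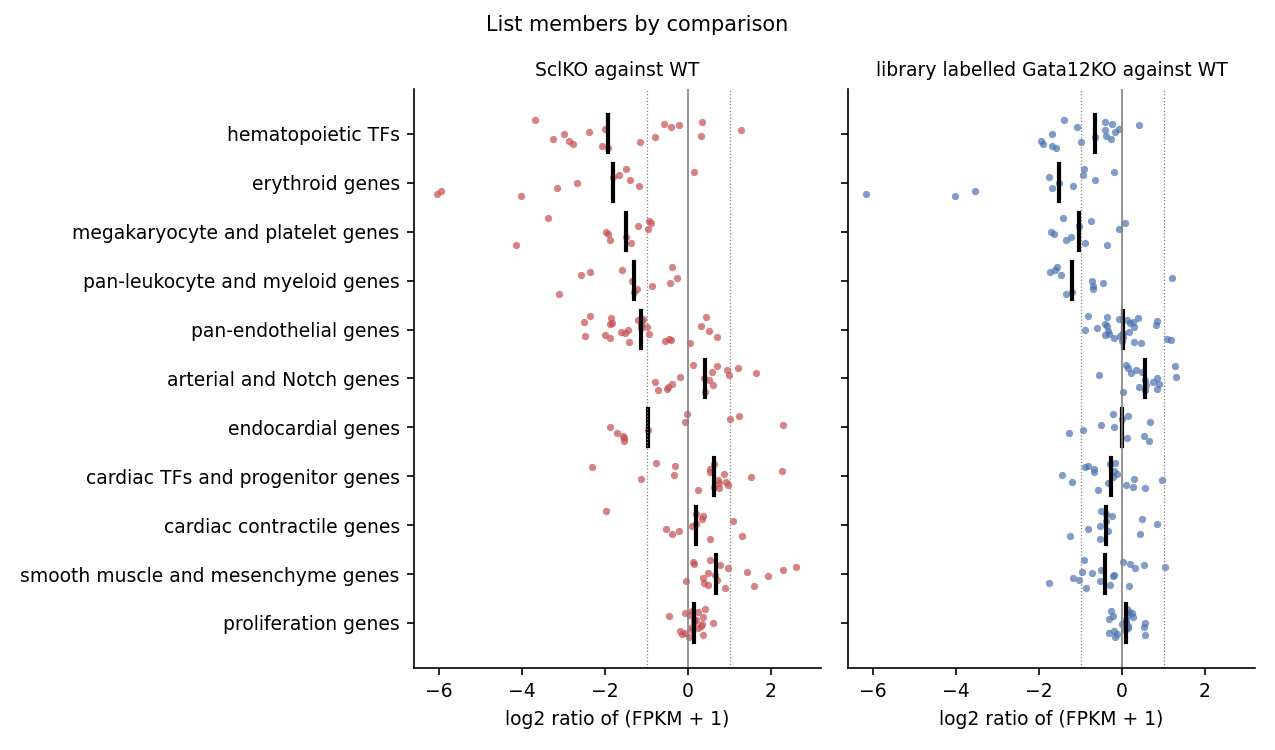
Log2 ratio of (FPKM + 1) of each expressed list member against WT (dots) and the list's median (black bars), for SclKO and for the library labelled Gata12KO, with dotted lines at 2-fold. Pan-endothelial genes had a median of -1.14 in SclKO and 0.03 in the library labelled Gata12KO, while erythroid genes had -1.80 and -1.53.

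In the library labelled Gata12KO against WT, many blood transcripts were lower, while of 27 pan-endothelial transcripts 2 were higher, 0 lower and 25 between. This comparison was meant to give the target genes of Gata1 and Gata2. All of its directions come from a library whose knockout could not be checked, as its Gata1 and Gata2 levels were not lower than in WT. By the size rule 85 genes were higher and 415 lower. Gata2 itself was among the 10 highest genes, together with Ero1a, which forms disulfide bonds (27.0 FPKM in WT and 103 in the library labelled Gata12KO), and the glycolytic Hk2 (4.29 and 16.7). Eno1 (25.5 and 131), the highest after the Y-linked Uty and Ddx3y, has near-identical copies, so its value is uncertain. Lowest were Hba-x (71.3 in WT and listed at 0), the pseudogene Rpl34-ps1 (44.2 and 1.46), Hba-a2, Hbb-bh1 (76.8 and 5.66) and the imprinted noncoding RNA Meg3 (18.4 and 0.749). As a copy of a ribosomal protein gene, Rpl34-ps1 has an uncertain value too.

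Erythroid genes were lower in 7 of 11 members of the library labelled Gata12KO, with a median of -1.53, which became -1.04 after the length trend was removed. Alas2, the first enzyme of heme synthesis in red cells, had 6.30 FPKM in WT and 1.53 there. Hematopoietic transcription factors were lower in 6 of 17 members, with none higher and a median of -0.66. They were Spi1, a myeloid regulator (6.58 and 0.954), Myb (6.77 and 1.06), Nfe2 (8.60 and 1.96), Gfi1b (3.34 and 0.358), Runx1 (4.56 and 0.854) and Myct1 (23.6 and 8.31). Lyl1 (21.3 and 17.5) and Hhex (37.9 and 35.8) lay between. Megakaryocyte and platelet genes were lower in 6 of 11 members (median -1.04), among them F10 (11.7 and 3.77) and Plek (3.14 and 0.267), while Itga2b had 22.8 and 17.6. Pan-leukocyte and myeloid genes were lower in 6 of 11 and higher in 1, Lcp1 (3.47 and 9.37), with a median of -1.21. Alox5ap (21.8 and 5.79) and Cd34 (18.9 and 5.50) were among the lower members. All 4 medians lay below all of the random lists, with or without the length trend. Its removal brought the megakaryocyte and platelet median to -0.81 and the pan-leukocyte and myeloid median to -0.75, and took Hbb-b2 (-1.18 became -0.54), Pf4 (-1.35 became -0.71), Lyz2 (-1.21 became -0.75) and Tyrobp (-1.48 became -0.85) below the 2-fold limit. Over all measured members the 4 medians were -0.24, -0.39, -0.17 and -0.25. Here too, fewer cells that express blood genes cannot be told from lower levels per cell.

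Of pan-endothelial genes, 2 of 27 were higher in the library labelled Gata12KO, the VEGF receptors Kdr (42.1 FPKM in WT and 96.3) and Flt1 (8.72 and 19.6), and none was lower. The call of Flt1 ended after the length trend was removed (1.08 became 0.97). The median was 0.03 (percentile 97.3, and 0.17 at 98.6 after the length trend was removed). Cdh5 had 116 and 141, Tek 62.9 in both and Nos3 17.7 and 21.4. Arterial and Notch genes had a median of 0.55 (0.69 after the length trend was removed), above all of the random lists, with Jag2 (1.32 and 4.76) and Foxc2 (1.97 and 6.14) higher and 15 of 17 between. Venous and lymphatic genes had Nr2f2 (4.07 and 10.3) and Stab1 (3.14 and 7.57) higher among 10 members and a median of 0.23 (percentile 97.4, and 83.3 after the length trend was removed, which also ended the call of Stab1, at 1.05 before and 0.86 after). Endocardial genes had a median of 0.00 (percentile 69.2), with Nrg1 (2.87 and 0.605) lower, and Scl complex partners had 0.10 (percentile 94.6).

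Cardiac transcription factors and progenitor genes had a median of -0.26 (percentile 4.98) in the library labelled Gata12KO, with Hand2 (54.5 FPKM in WT and 19.4) and Tbx2 (3.97 and 1.15) lower among 18 members and 16 between. Cardiac contractile and cardiomyocyte genes had a median of -0.39 (percentile 2.59), with Tnni1 lower (10.2 and 3.68). After the length trend was removed that median became 0.04 and the call of Tnni1 ended (-1.26 became -0.81). Smooth muscle and mesenchyme genes had a median of -0.40 (percentile 0.66, with -0.27 after the length trend was removed), with Acta2 (42.1 and 11.7), Col1a1 (9.66 and 4.19) and Col1a2 (11.3 and 4.40) lower and Foxf1 (0.722 and 2.53) higher. Primitive streak and early mesoderm genes had a median of -0.02 (percentile 57.2, and 0.34 at 98.7 after the length trend was removed), pluripotency genes -0.41 (5.17), endoderm and epithelial genes -0.38 (4.32, and -0.12 at 20.1 after the length trend was removed) and neuroectoderm genes -0.05 (45.2). The keratins Krt8 (40.8 and 17.1) and Krt18 (45.2 and 18.1) were lower, and both calls ended after the length trend was removed (log2 ratios of -1.21 and -1.27 became -0.97 and -0.93). Of pluripotency genes, Dppa4 (-1.26 became -0.92) and Dppa5a (-1.27 became -0.62) also went below the 2-fold limit. Proliferation genes had 0 of 21 past the rule and a median of 0.11 (percentile 99.8, or 96.2 among unmatched lists). Immediate early and stress genes had -0.26 (12.2) and housekeeping genes -0.29 (52.9), with 0 members past the rule in either, and the medians were -0.10 and 0.01 after the length trend was removed.

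Ratios in this comparison followed transcript length. Genes with transcripts of 312 to 1239 nt had a median log2 ratio of -0.52 and those of 5625 to 23495 nt a median of 0.14, and the Spearman correlation across 10992 genes, which are not independent replicates, was 0.439. In SclKO against WT the same correlation was 0.237. The lower genes had a median length of 1200 nt against 2813 nt for expressed genes. With the length trend removed, a step chosen after seeing the data, 151 genes were higher and 177 lower, and the lower share went from 83% to 54.0%. Removing length and GC trends together gave 155 higher and 176 lower (53.2% lower). Rescaling by median ratios gave 126 higher and 323 lower, a lower share of 71.9%. Rescaling to the library sum (TPM) turned the balance, with 1348 higher and 118 lower (8.05% lower), since it moved the median gene up by 0.60 on the log2 scale (-0.11 in SclKO against WT and 0.72 against SclKO). In each library that sum rests mostly on entries under 300 nt, which held 66.7% of it in WT and 56.5% in the library labelled Gata12KO. Over transcripts of 300 nt or longer the same rescaling gave 547 higher and 365 lower, a lower share of 40.02%. It raised every value while the pseudocount stayed at 1, so this share mixes the scaling between libraries with a smaller weight of the pseudocount. All list medians given here are on the deposited scale.

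**Figure D3:**
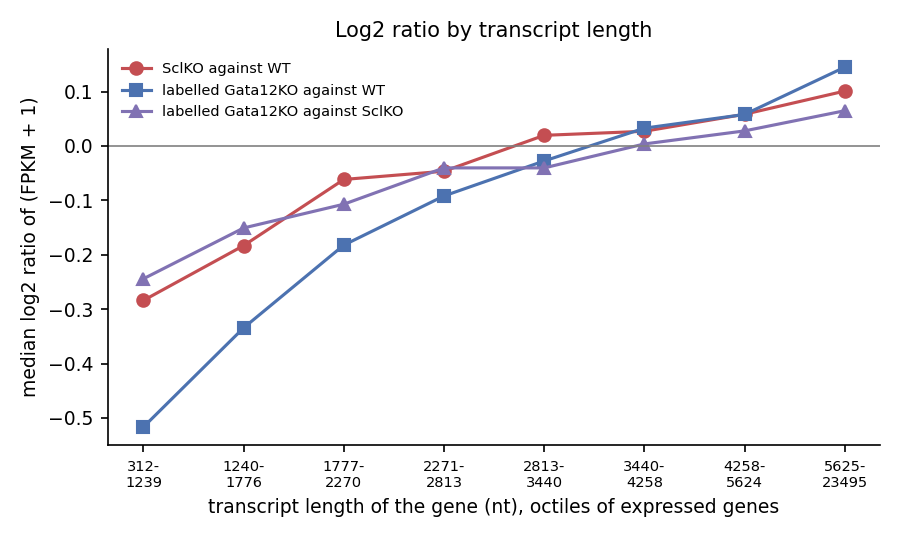
Median log2 ratio of (FPKM + 1) for the 3 comparisons (lines) in octiles of transcript length (horizontal axis, nt), over expressed genes with transcripts of 300 nt or longer. The library labelled Gata12KO against WT ran from -0.52 in the shortest octile to 0.14 in the longest, and SclKO against WT from -0.28 to 0.10.

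The library labelled Gata12KO was then set directly against SclKO, without WT, to find where these libraries differ. Many endothelial transcripts were higher and many mesenchymal transcripts lower in the library labelled Gata12KO than in SclKO, with 375 genes higher and 416 lower. Pan-endothelial genes were higher in 18 of 27 members, with none lower and a median of 1.55, above all of the random lists. Nos3 had 2.31 FPKM in SclKO and 21.4 in the library labelled Gata12KO, Esam 14.9 and 85.2, Cd93 1.13 and 9.14, and Icam2 13.6 and 58.3. Smooth muscle and mesenchyme genes were lower in 11 of 18, with none higher and a median of -1.44, below all of the random lists. Cdh11 had 25.9 and 2.84, Snai2 31.8 and 5.36, Col3a1 8.06 and 1.04, and Acta2 55.1 and 11.7.

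Cardiac transcription factors and progenitor genes were lower in 7 of 18 members, including Irx3 (16.9 FPKM in SclKO and 2.24 in the library labelled Gata12KO) and Hand1 (209 and 61.7), and higher in 2, Mef2c (1.77 and 6.40) and Fgf10 (0.913 and 4.13), with a median of -0.89, below all of the random lists. Cardiac contractile and cardiomyocyte genes had a median of -0.43 (percentile 0.78, and -0.28 at 2.30 after the length trend was removed), with Tnni1, Tpm1 and Tnnt2 lower and Cox7a1 higher, the call of Tnnt2 ending after the length trend was removed (-1.06 became -0.86). Hematopoietic transcription factors were higher in 5 of 17 (Lyl1, Myct1, Cbfa2t3, Hhex and Nfe2) and lower in 1 (Gata3), with a median of 0.41 (percentile 99.99, and 0.56 after the length trend was removed). Spi1 (0.0312 and 0.954), Myb (0.143 and 1.06) and Runx1 (0.452 and 0.854) were low in both. Erythroid genes had a median of 0.57, megakaryocyte and platelet genes 0.48, and pan-leukocyte and myeloid genes 0.55, all at percentiles of 99.8 or more, with 0.04, 0.15 and 0.01 over all measured members. Itga2b had 0.333 FPKM in SclKO and 17.6 in the library labelled Gata12KO. Venous and lymphatic genes had a median of 0.68, above all of the random lists, endocardial genes 0.44 (99.92) and arterial and Notch genes 0.05 (79.0, and 0.19 at 95.8 after the length trend was removed), while Scl complex partners had 0.24 (99.59). The vascular lists held calls in both directions. Venous and lymphatic genes had 3 of 10 higher and 2 lower, and endocardial genes 4 of 11 higher and 3 lower. Arterial and Notch genes had 5 of 17 higher and 3 lower. Medians of the other lists were -0.51 for primitive streak and early mesoderm genes (percentile 0.49, and -0.31 at 2.93 after the length trend was removed), -0.70 for endoderm and epithelial genes (0.04, with -0.53 at 0.1 after its removal and 0.0473, of the other sign, over all measured members), -0.12 for pluripotency genes (31.1), 0.24 for neuroectoderm genes (81.2), -0.08 for proliferation genes (73.9), -0.12 for immediate early and stress genes (34.3) and -0.07 for housekeeping genes (82.6, and 0.09 after its removal). Lower calls made up 52.6% of the total, against 5.31% after rescaling to the library sum (2174 higher and 122 lower), 40.7% over transcripts of 300 nt or longer (833 higher and 571 lower) and 40.1% with length and GC trends removed (444 higher and 297 lower). Of these, the rescaling over transcripts of 300 nt or longer also lowered the weight of the pseudocount.

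SclKO and the library labelled Gata12KO, whose Gata1 and Gata2 levels were not lower than in WT, shared a set of genes lower than in WT, with blood regulators among them. Of the 470 genes lower in SclKO, 118 were also lower in the library labelled Gata12KO (25.1%), including Runx1, Myb, Spi1, Nfe2, Gfi1b, Myct1, Alas2, Hba-x and Mpo. With the length trend removed the overlap was 69. Independent sets of the reported sizes would share 17.6 genes, and libraries simulated as equal to WT shared 0.61 on average and at most 3. Of the 470, 5 were higher in the library labelled Gata12KO. Of the 235 genes higher in SclKO, 22 were also higher in that library, and the number was 41 with the length trend removed. Here independent sets would share 1.80 and simulated libraries shared 0.71 on average, and 6 of the 235 were lower in that library. Neither reference includes a difference of the WT culture, which would add genes to both overlaps. Of the 22, 3 are the Y-linked Ddx3y, Uty and Eif2s3y, for which WT stands apart from both other libraries, and 19 remain without them. Genes lower in SclKO had a median log2 ratio of -1.45 there, and genes higher in SclKO one of 1.27. In the library labelled Gata12KO the medians of the same genes were -0.52 and 0.15. Because the genes were chosen by their ratio to the same WT library, noise in WT draws these medians the same way.

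Across 10992 genes the ratios to WT of both libraries had a Pearson correlation of 0.424, and libraries simulated as equal to WT gave 0.503. The shared WT sets the simulated value by construction, and changes in only 1 of the libraries lower the observed value. The correlation therefore cannot tell whether the libraries share changes. The covariance of the ratios was 0.117, above the 0.0482 simulated, and the correlation was 0.384 with the length trend removed. The simulation took its noise from the ratios between SclKO and the library labelled Gata12KO and held no length trend. The excess of the covariance therefore cannot tell whether the libraries share changes either. Both comparisons use the same WT library, which cannot be split, so part of the shared genes may come from it.

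**Figure D4:**
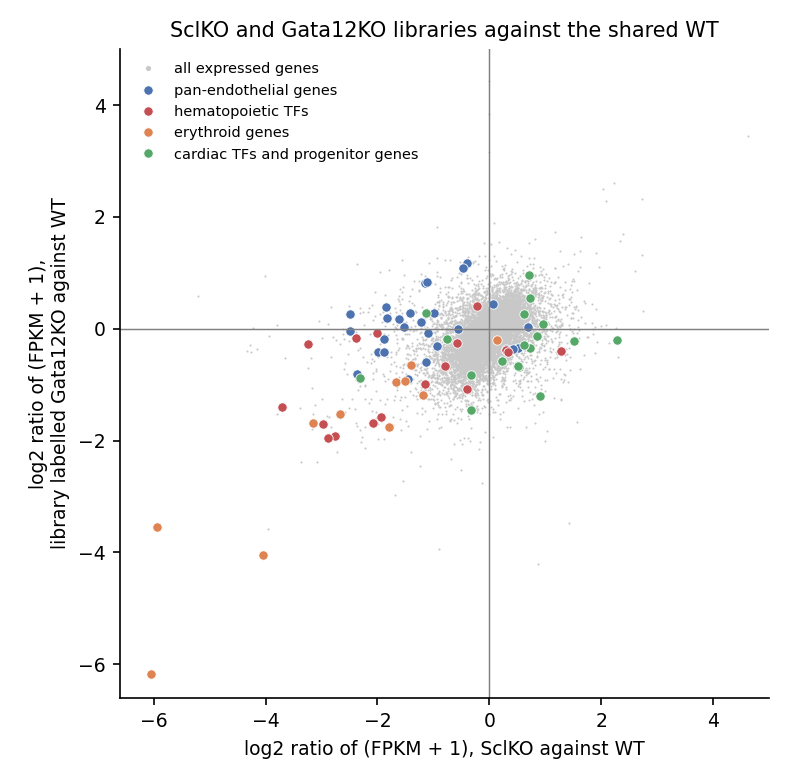
Log2 ratio of (FPKM + 1) against WT in SclKO (horizontal axis) and in the library labelled Gata12KO (vertical axis), 1 dot per expressed gene with a transcript of 300 nt or longer, with members of 4 lists coloured. Medians on the horizontal and vertical axes were -1.14 and 0.03 for pan-endothelial genes, whose members spread to both sides, and -1.80 and -1.53 for erythroid genes.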

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

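Removal of the length trend, alone or with GC, rescaling over transcripts of 300 nt or longer and the minimum taken without the library labelled Gata12KO were chosen after the result was seen, and the other alternatives were planned. No paired analysis was possible and no library was left out, because each group holds 1 library. In this part Gata12KO stands for the library labelled Gata12KO, whose Gata1 and Gata2 values were not lower than in WT.

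Of 106 alternatives for 8 counts of genes, 61 stayed within 1.5 times the reported count and 45 did not. Median-ratio rescaling, no condition on bounds, no transcripts under 300 nt and the minimum without the library labelled Gata12KO left each count they were run for within 1.5 times. Omitting the expression minimum gave identical counts, since the 2-fold rule with a pseudocount of 1 already requires an FPKM of 1. Below, counts are higher and lower in SclKO against WT, in Gata12KO against WT and in Gata12KO against SclKO, then higher and lower in both libraries against WT. A pseudocount of 0.1 gave 475 and 744, 229 and 714, 595 and 690, then 71 and 216. A pseudocount of 5 gave 82 and 184, 22 and 158, 132 and 161, then 10 and 28. A 4-fold rule, stricter by construction, gave 15 and 114, 9 and 26, 82 and 44, then 5 and 9. The pseudocounts act by construction, as a smaller one widens the ratios of genes with low values. A minimum of 5 FPKM left 76 genes lower in both libraries against WT.

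Rescaling to the library sum (TPM) gave 1348 higher and 118 lower in Gata12KO against WT, 2174 and 122 against SclKO, and 66 and 68 in both libraries against WT. A single entry of 96 nt held 41.4% of that sum in WT, 42.7% in SclKO and 30.0% in Gata12KO. The most abundant transcript per gene gave 177 higher in Gata12KO against WT and 90 higher in both libraries against WT, and the cause was not tested. Removing the length trend gave 151 higher and 177 lower in Gata12KO against WT, and 41 and 69 in both libraries against WT. With GC removed as well, these were 155 and 176, and 39 and 72. Rescaling over transcripts of 300 nt or longer gave 640 higher in SclKO against WT and 547 higher in Gata12KO against WT. The same rescaling gave 833 higher in Gata12KO against SclKO and 128 higher in both libraries against WT. It raised every value while the pseudocount stayed the same, so the pseudocount weighed less. The scaling between libraries was not separated from this smaller weight.

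For the medians of 57 combinations of list and comparison, 279 of 399 alternatives stayed close to the reported value, 118 moved and 2 reversed. Hematopoietic transcription factors in SclKO had medians of -2.55 with a pseudocount of 0.1, -0.76 with 5, -1.51 with the most abundant transcript and -0.64 over all measured members. In Gata12KO these were -0.82, -0.32, -0.40 and -0.39. Erythroid genes in SclKO had -4.69 with a pseudocount of 0.1, -0.64 with 5 and -0.29 over all measured members. In Gata12KO they had -2.10, -0.57 and -0.24, with -1.83 relative to the median gene after rescaling to the library sum and -1.04 without the length trend. Megakaryocyte and platelet genes had -2.99, -0.69 and -0.41 in SclKO with pseudocounts of 0.1 and 5 and over all measured members, and -1.61, -0.45 and -0.17 in Gata12KO. Pan-leukocyte and myeloid genes had -2.36, -0.47 and -0.26 in SclKO, and -1.62, -0.38 and -0.25 in Gata12KO. Pan-endothelial genes had -1.26 and -0.93 in SclKO with pseudocounts of 0.1 and 5, and 0.17 in Gata12KO without the length trend. Cardiac transcription factors had 0.42 in SclKO with a pseudocount of 5 and 0.23 over all measured members, and -0.14 in Gata12KO over all measured members. Over all measured members smooth muscle and mesenchyme genes had 0.49 in SclKO, -0.21 in Gata12KO and -0.79 in Gata12KO against SclKO, endocardial genes -0.36 in SclKO, and arterial and Notch genes 0.22 in SclKO and 0.41 in Gata12KO. Medians over all measured members include genes that are near 0 in each library, which draws them towards 0 by construction. The 2 reversed medians, both over all measured members, were primitive streak and early mesoderm genes in SclKO against WT (-0.0051) and endoderm and epithelial genes in Gata12KO against SclKO (0.0473). Of the percentiles, 103 of 114 alternatives stayed on their side of the limits and 11 did not. For 283 ratios of named genes, 1248 of 1698 alternatives stayed close, 450 moved and 0 reversed.

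Depth limits the genes with low values. Of the entries, 8381 were listed at 0 in WT, 9004 in SclKO and 7805 in Gata12KO, at 31.6, 28.3 and 50.3M implied fragments.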

Other observations

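The lists of Hox, hypoxia, signalling pathway, extracellular matrix, ribosomal protein, Y-linked and imprinted genes and the tests of the 3 patterns below were chosen only after the result was seen, while the erythroid, pan-endothelial and mesenchyme lists were planned. Values are FPKM in WT, SclKO and the library labelled Gata12KO, in that order. In the next paragraph, members whose values had been printed before they were named for a list are left out of its medians and counts.

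Of 14 expressed Hox genes, which pattern the body axis, 4 were lower in SclKO than in WT and 0 higher, with a median log2 ratio of -0.82, below all of the random lists. In the library labelled Gata12KO, 3 were higher than in WT and 0 lower, with a median of 0.44 (percentile 99.99), and against SclKO the median was 1.26. Hoxb6 had 9.16, 3.27 and 15.5. Hoxc8 (0.753, 1.66 and 0.669) and Hoxc9 (0.413, 1.19 and 0.230) were above WT in SclKO, though neither passed the size rule. Many expressed Hox genes are Hoxb genes, which lie together on chromosome 11. Random lists of single genes do not reflect neighbours that change together, so these percentiles may overstate how unusual the medians are. Of 32 expressed hypoxia response and glycolysis genes, 0 were higher or lower by the size rule in the library labelled Gata12KO than in WT, with a median of 0.41, above all of the random lists. In SclKO 1 was higher and 1 lower than in WT, with a median of -0.30 (percentile 1.56), and the median of the library labelled Gata12KO against SclKO was 0.50. Of 22 expressed genes of Wnt, BMP, TGF-beta and FGF pathways, 3 were higher and 0 lower in SclKO, with a median of 0.64, above all of the random lists. Lef1, a factor of Wnt signalling, had 3.38, 9.10 and 4.69, and Dkk1 had 4.03, 10.7 and 3.92. In the library labelled Gata12KO the median was 0.02 (percentile 83.8), and against SclKO -0.61. Of 20 expressed extracellular matrix genes, 2 were higher and 1 lower in SclKO, with a median of 0.25 (percentile 99.6). In the library labelled Gata12KO 0 were higher and 2 lower than in WT, with a median of -0.18 (28.2), and against SclKO the median was -0.69. Of 84 ribosomal protein genes, 4 reached 1 FPKM in any library, among them Rps23 (1172, 809 and 738). Whether the cells lack the other transcripts or the deposited values miss them was not tested. A value near 0 in these libraries may therefore not mean absence.

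Y-linked genes had lower values in WT than in either other library. Ddx3y had 1.25, 8.17 and 11.8, Uty 0.954, 8.16 and 10.9, and Eif2s3y 7.26, 34.3 and 39.4. WT held 15.3%, 11.7% and 21.2% of the SclKO values of these genes, in that order.

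The first pattern weighed is that Gata1 and Gata2 were not lower in the library labelled Gata12KO. An exchange of its label with SclKO is argued against by Tal1, which was 24.4-fold higher there than in SclKO. An exchange with WT is argued against by erythroid genes, with a median log2 ratio of -1.53 against WT. Targeted alleles that still give a transcript may account for it, and with Gata2 at a log2 ratio of 1.82 and 1 value per gene, without values per exon, this stays open. A library from another line also stays open.

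The second pattern is that pan-endothelial genes were lower in SclKO, where a lower share of endothelial cells is a technical explanation. A common factor for the members is argued against by the interquartile range of their log2 ratios, 1.33, against a median of 0.51 and an upper limit of 0.77 in random lists, and by Eng, Etv2, Plvap and Adgrf5, with bounds above those of WT. A lower share still stays open, since smooth muscle and mesenchyme genes had a median of 0.67 in SclKO, with Cdh11, Col3a1 and Pdgfrb higher, and cells that express part of the members may widen the range, although the sort for Tie2 and CD31 would remove cells without these antigens. Transcript length is argued against by a median of -1.15 after the length trend was removed. Loss of Scl, which the design names, stays open, as does a difference between cultures.

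The third pattern is that some imprinted genes, expressed from 1 parental copy, differed between the libraries, as Grb10 (46.1, 0.279 and 69.6), Meg3 (18.4, 50.7 and 0.749) and Rian (3.42, 12.1 and 0.384) did. Whether imprinted genes as a class differ more than other genes stays open. Over all 45 expressed members the median absolute log2 ratio of the library labelled Gata12KO against SclKO was 0.62, above all of the random lists, but 5 members had prompted the list. The other 40, named before their values were printed, were at percentile 99.97 (99.87 for SclKO and 71.6 for the library labelled Gata12KO against WT). The 71.6 became 99.5 after the length trend was removed. Which members these 40 were was worked out afterwards, with other divisions tried before. The 25 of a first query lay above all of the random lists in the library labelled Gata12KO against SclKO (99.99 and 84.0 against WT). The 15 of a second query lay at percentile 60.97 (59.98 and 24.5 against WT). With the length trend removed, the 84.0 became 99.1, and the second query stood at 41.0 (34.1 and 90.3 against WT).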
